A study of Mus musculus with 2 samples.

How the data were processed

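The series holds 2 chromatin immunoprecipitation sequencing libraries from mouse T helper 17 (Th17) cells, 1 made with an antibody to STAT3 and 1 with a mixture of antibodies to STAT5A and STAT5B. Naive CD4 T cells of C57BL/6J mice had been sorted and cultured for 3 days with T cell receptor and CD28 antibodies, IL-6 at 20 ng/ml and TGF-beta at 2 ng/ml, per the labels. The labels also list antibodies to IL-4 and IL-2 in the culture, the latter in IU/ml, a unit usual for IL-2 itself, so whether IL-2 was blocked before restimulation is left open. Cells were then given IL-6 (40 ng/ml) before the STAT3 library or IL-2 (200 IU/ml) before the STAT5 library for 30 minutes, and were fixed with 1% formaldehyde. Libraries were amplified for 18 cycles and cut from a gel at about 250 bp including adapters, per the labels' protocols. The antibody and the cytokine differed together, and neither an input or IgG library nor a second library of either kind was analysed here.

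Each deposited file is a list of aligned reads with 1 line per read and no header, and holds chromosome, start, end, a match descriptor, a score and strand. The genome build is mm9, per the submitters' processing notes, and the aligner, its settings and any peak caller are not given in the sources used here. Every read was 25 nt long with start and end both counted from 1. The deposited score was 0 in all lines and was not used. The descriptor gave an exact match for 98.1% of STAT3 reads and 98.2% of STAT5 reads. The deposited files hold at most 1 read per position and strand (0% of the nuclear reads were redundant), and the step that led to this is not given in the sources used here. Read counts therefore cannot exceed 400 in a window of 200 bp or 800 in 400 bp, which compresses differences at the tallest sites.

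All further steps were computed from the reads with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The fragment length was the shift between 60 and 400 bp with the highest smoothed correlation of plus and minus strand 5′ ends on chromosomes 1, 11 and 19, and came to 92 bp for STAT3 and 102 bp for STAT5. Read 5′ ends were moved by 50% of it to the fragment centre. Centres were counted in windows of 200 bp moved by 50 bp over chromosomes 1 to 19, X and Y. A window was called when it held at least 5 reads, its count was at least 4-fold over the largest of the genome-wide, 5 kb and 10 kb means, and its Poisson p, 1-sided and adjusted by the Benjamini-Hochberg method over windows with a read, was at or below 1e-05. The genome-wide mean was taken over the 2360778000 bp of 1 kb bins that held a read of either library. The 5 kb and 10 kb means included the window itself and any neighbouring sites, so a tall site near others could go uncalled. Called windows within 100 bp were joined into regions, and 104 STAT3 and 182 STAT5 regions with over 80% of their summit reads on 1 strand were left out. Without a control library, these regions include any place that yields more reads than its surroundings for reasons other than the antibody.

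Regions of the libraries were called overlapping when they shared at least 1 bp, and overlap was compared with 100 random circular shifts of the STAT3 regions along each chromosome. Overlapping regions were merged into sites centred on the member summit with the highest RPM. Reads of both libraries were counted in 400 bp around each centre and scaled to RPM by the nuclear reads of each library. The ratio of the scaled counts was given an exact conditional (Clopper-Pearson) 95% interval, and a site was called higher in 1 library when the interval lay wholly beyond 2-fold. With 1 library per group no p-value was computed between them, and the calls compare these libraries, not the conditions. All intervals and floors cover counting error only, and the floor for a count of 0 was 3 reads per library. Counting error was also gauged by splitting each library at random into equal parts. Flank levels were counted in 400 bp windows 5 kb to either side of a site where these met no region.

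Alternatives changed the thresholds, the local mean, the strand filter, the fragment length, the depth, the overlap rule, the scaling, the ratio limit and the counting width, 1 at a time. Designs, 11 gene lists, the rule for named regions and all alternatives except 3, named with their values, were fixed before the data were examined. The rule named the 10 regions of each library with most reads in 400 bp around the summit, and the 10 sites on each side with the largest ratio by the interval bound nearest to 1. The rule's part on genes, and the planned results on gene lists, position relative to genes and the STAT sequence motif, need an annotation and sequence of mm9. The gene table used here is on GRCm38, coordinates were not converted between builds, and regions are therefore given by mm9 position without gene names. The caller was tested on simulated reads for chromosome 19 at the STAT3 background, where it found 92% of 200 planted sites of 20 reads, 100% of those of 40 reads and 13.5% of those of 10 reads, and 0 of its 411 regions lay away from a planted site. Planted sites lay in separate 10 kb bins, and the background reads were spread evenly at random within each bin. The simulation therefore does not show how the caller performs where sites lie close together or the background is uneven. In 10000 simulated sites with 30 reads in 1 library, 95.1% were called higher at a true ratio of 4, 1.91% at a ratio of 2 and 0% at equal levels.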

Results

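Chromatin immunoprecipitation sequencing placed STAT3 and STAT5, transcription factors that become active downstream of IL-6 and IL-2 respectively, along the genome of Th17 cells, the CD4 T cells that make IL-17. The STAT3 library held 20788823 aligned reads and the STAT5 library 17968199, of which 20784388 and 17963766 lay on nuclear chromosomes, each at its own position and strand. There was 1 library per antibody, so every difference below lacks a replicate check, and its intervals cover counting error only. Positions are on mm9 and counted from 1.

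Both antibodies gave many sharp regions. STAT3 reads were enriched in 56521 regions and STAT5 reads in 70235, with a median width of 350 bp in either library. These numbers depend on the threshold: a minimum of 8-fold left 24023 STAT3 and 41582 STAT5 regions, and the genome-wide mean alone gave 90151 and 101637. STAT5 regions held 36.2% of the STAT5 reads (exact 95% interval 36.1 to 36.2%) on 1.11% of the length in which reads were placed, and STAT3 regions held 21.4% of the STAT3 reads (21.4 to 21.4%) on 0.871%. The median STAT3 region had 51 reads in 400 bp around its summit (quartiles 30 and 93), and the median STAT5 region 47 (26 and 99). The correlation of the strands, a measure of how far reads pile up as fragments, peaked at 0.0733 for STAT3 and 0.158 for STAT5, against 0.00918 and 0.0147 at a shift of 1500 bp. At their tallest windows 1910 STAT3 regions and 5727 STAT5 regions had a read at 200 or more of the 400 combinations of position and strand in 200 bp, and in 21 STAT5 regions every one was taken.

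Regions were spread over all autosomes. They were densest on chromosome 11, with 34.4 STAT3 and 40.7 STAT5 regions per Mb, against medians over the 19 autosomes of 21.7 and 26.7. Chromosome 14 was the sparsest autosome, with 17.0 STAT3 and 21.9 STAT5 regions per Mb. Chromosome X had 7.37 STAT3 and 9.96 STAT5 regions per Mb. All reads, in regions or not, numbered 11.4 STAT3 reads per kb on chromosome 11, 6.69 on chromosome 14 and 3.67 on chromosome X.

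The series asks where STAT3 and STAT5 bind in the same kind of cell. Most STAT3 regions were also STAT5 regions: 41000 of 56521 (72.5%, exact 95% interval 72.2 to 72.9%) overlapped a STAT5 region, and 40989 of 70235 STAT5 regions (58.4%, 58.0 to 58.7%) overlapped a STAT3 region. With regions of at least 8-fold only, the shares were 67.0% of STAT3 and 38.7% of STAT5 regions. Random shifts gave 2.05% (range 1.86 to 2.21% over 100 shifts) of STAT3 regions and 1.65% (1.49 to 1.78%) of STAT5 regions. The shifts place regions anywhere on a chromosome, including where few reads fall. Without a control library, this contrast cannot separate shared binding from places that yield more reads whatever the antibody. Each library was also split at random into equal parts. Of the regions called in one part of the STAT3 reads, 82.5% overlapped those of the other part, and for STAT5 this was 83.7%, whereas 67.5% of the regions of a STAT3 part overlapped those of a STAT5 part, and 53.8% of the regions of a STAT5 part overlapped those of a STAT3 part. Among the tallest 20000 regions of each library the overlap was 52.4% for STAT3 and 52.3% for STAT5, a comparison chosen after the data were seen.

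Overlap was highest among the tallest regions of either library. Of the 1000 tallest STAT3 regions 94.1% (exact 95% interval 92.5 to 95.5%) overlapped a STAT5 region, and of those ranked beyond 20000 65.0% (64.5 to 65.5%) did. For STAT5 the shares were 89.9% (87.9 to 91.7%) and 54.0% (53.6 to 54.4%). Of the 59 STAT3 regions among the tallest 1000 without an overlap, 58 still had 50 or more STAT5 reads at the summit, and of the 101 such STAT5 regions 49 had 50 or more STAT3 reads. The medians were 157 STAT5 reads (30 to 701) and 44 STAT3 reads (7 to 647), so a missing region need not mean few reads.

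**Figure D1:**
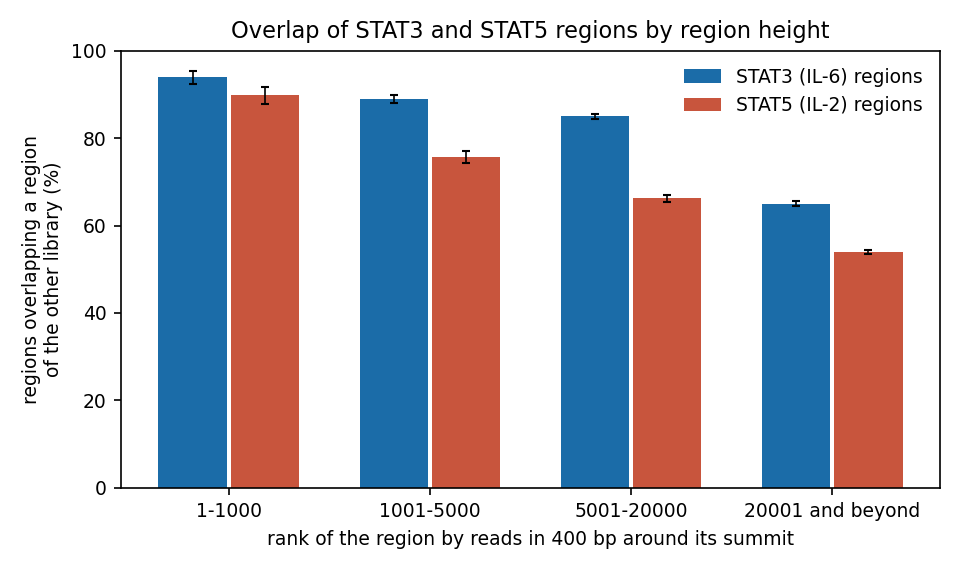
Share of regions (%) that overlap a region of the other library, by rank of the region by reads in 400 bp around its summit; blue bars are STAT3 regions after IL-6 and red bars STAT5 regions after IL-2, with exact 95% intervals for counting error. The share falls from 94.1% to 65.0% for STAT3 and from 89.9% to 54.0% for STAT5.

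Merging the regions gave 85657 sites, of which 40890 (47.7%) were regions with both antibodies, 15521 (18.1%) with STAT3 only and 29246 (34.1%) with STAT5 only. At sites called with both, the median count was 60 STAT3 and 56 STAT5 reads, which is 2.89 and 3.12 RPM, and the mean counts were 16.9-fold and 27.5-fold over the flanks. A site missing from one list was often not empty in that library. Regions were called against local means that include neighbouring sites, so these classes depend on that rule as well as on the reads. With the genome-wide mean alone, the overlap was 75.8% of STAT3 and 67.7% of STAT5 regions. Of the STAT3-only sites 84.1% (exact 95% interval 83.5 to 84.7%) had STAT5 reads over 2 times the flank mean of 3.76, against 9.74% of flank windows. Of the STAT5-only sites 48.6% (48.0 to 49.2%) had STAT3 reads over 2 times the flank mean of 4.59, against 9.02% of flank windows. STAT3 reads were at or below the flank mean at 25.5% of the STAT5-only sites (25 to 26.0%), against 67.0% of flank windows. STAT5 reads were so at 3.39% of the STAT3-only sites (3.11 to 3.69%), against 71.0% of flank windows.

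The centres of the read distributions were compared at shared sites. Over the 18540 shared sites with 50 or more reads of each antibody, the median position of the fragments differed by a median of 18 bp between a STAT3 part and a STAT5 part, and by 25 bp or less at 63.5% of sites. Random parts of the same library differed by 12 bp for STAT3 and 11.5 bp for STAT5, within 25 bp at 81.5% and 82.5% of sites. Parts of 1 library differ by counting error only, and no second library of the same antibody was analysed here to set beside the offset between the libraries. These sites were chosen for overlapping regions and counted around 1 common centre in 400 bp, which bounds the offset. Read counts over the 85657 sites correlated with Pearson's r = 0.436 on the log2(reads + 1) scale and Spearman's rho = 0.467 between a STAT3 part and a STAT5 part, against 0.929 and 0.945 between STAT3 parts and 0.938 and 0.931 between STAT5 parts. These correlations are across sites, which are not independent replicates. The sites were chosen for a region in at least 1 of these same libraries, which leaves out places low in both. The gap between the correlations depends on that choice.

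Far more sites were higher with STAT5 than with STAT3. On the RPM scale, 21595 sites (25.2%, exact 95% interval 24.9 to 25.5%) were more than 2-fold higher with STAT5 and 2063 (2.41%, 2.31 to 2.51%) with STAT3, while 61999 (72.4%) were not called. The STAT5-higher sites had a median of 84 STAT5 and 10 STAT3 reads, and the STAT3-higher sites 99 STAT3 and 20 STAT5 reads. Of the sites called with both antibodies, 5258 (12.9%) were higher with STAT5 and 725 (1.77%) with STAT3. Random parts of one library, compared in the same way, gave 5 and 2 such sites for STAT3 and 3 and 6 for STAT5, against 1332 higher with STAT3 and 17057 with STAT5 for a STAT3 part and a STAT5 part. The split depends on the scaling: when the libraries were scaled by reads in 10 kb bins without a region, 27915 sites were higher with STAT5 and 674 with STAT3. Scaling to a median ratio of 1 at sites called with both antibodies changed it little, to 21076 higher with STAT5 and 2218 with STAT3. With intervals beyond 1.5-fold in place of 2-fold, 27137 were higher with STAT5 and 4906 with STAT3.

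**Figure D2:**
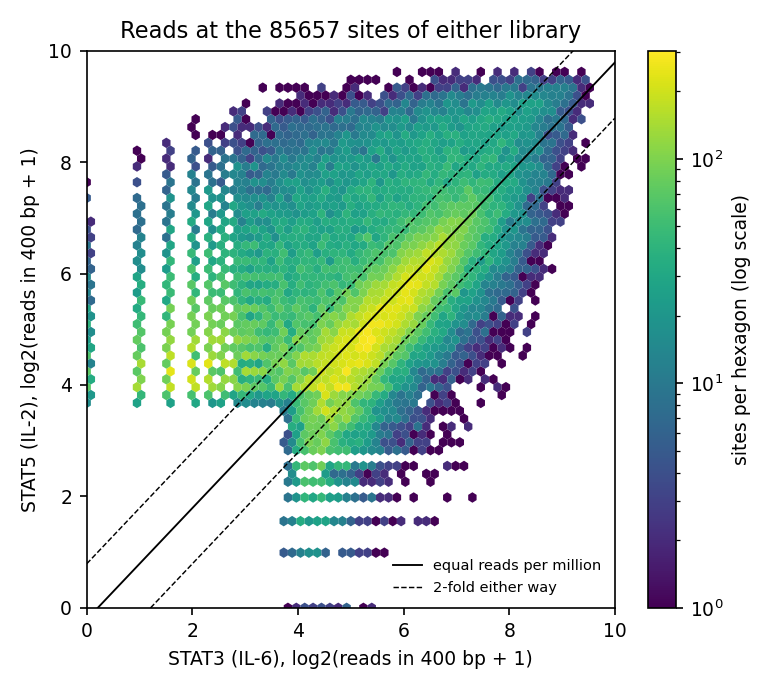
Reads in 400 bp at the 85657 sites, as log2(reads + 1), with STAT3 after IL-6 on the horizontal axis and STAT5 after IL-2 on the vertical axis; colour gives the sites per hexagon on a log scale, the solid line equal RPM and the dashed lines a 2-fold difference. The 21595 sites higher with STAT5 spread far to the left of the line, and fewer, 2063, are higher with STAT3.

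**Figure D3:**
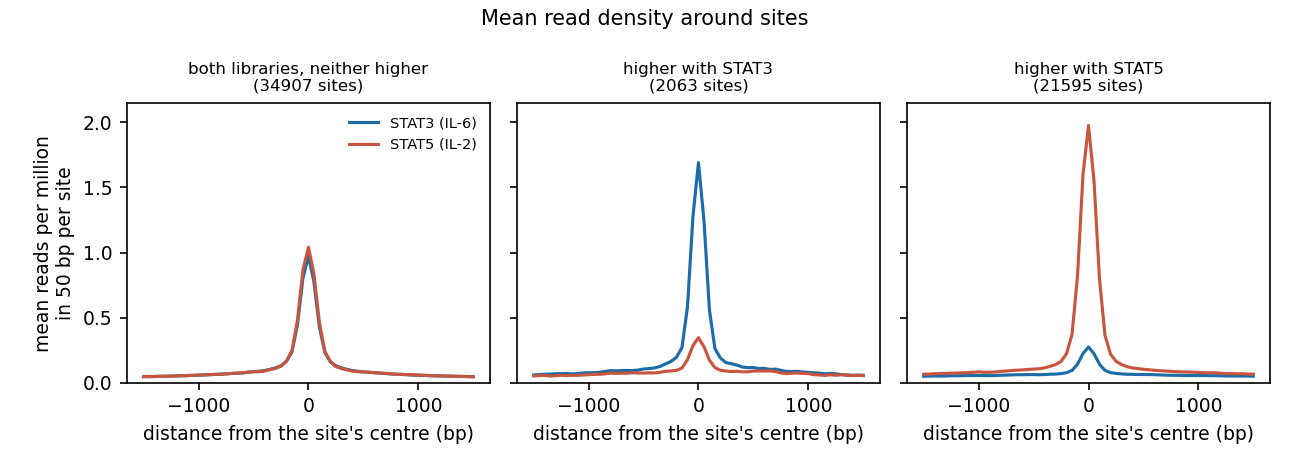
Mean RPM in 50 bp per site against the distance from the site's centre (bp), for STAT3 (blue) and STAT5 (red), with a band of 1 standard error over sites that is mostly thinner than the line. At sites with both regions and neither higher the centres reach 0.972 and 1.04, at STAT3-higher sites 1.69 and 0.347, and at STAT5-higher sites 0.275 and 1.97.

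The tallest STAT3 regions were mostly tall with STAT5 as well. The tallest lay on chromosome 10 from 95663750 to 95664399 and had 736 STAT3 and 675 STAT5 reads in 400 bp, a ratio of RPM of 0.942 (95% interval 0.848 to 1.05). Of the 10 tallest, 9 overlapped a STAT5 region and 8 were not called higher with either antibody. They included a region on chromosome 2 from 14234050 to 14234649 with 704 STAT3 and 522 STAT5 reads, and one on chromosome 4 from 8833850 to 8834499 with 703 and 512. On chromosome 11 the region from 98977200 to 98977749 had 689 STAT3 and 718 STAT5 reads, and on chromosome 10 the region from 7544350 to 7544949 had 686 and 708. On chromosome 9, from 123844050 to 123844499, there were 686 and 536 reads. The region on chromosome 14 from 54852850 to 54853399 had 691 STAT3 and 326 STAT5 reads, a ratio of 1.83 (1.60 to 2.10). STAT3 was higher at 2 of the 10, on chromosome 12 from 87046450 to 87046949 with 703 against 259 reads (ratio 2.35, interval 2.03 to 2.72), and on chromosome 11 from 52127500 to 52128099 with 681 against 231 (2.55, 2.19 to 2.97). Scaling by bins without a region lowers STAT3 to 0.723 of its RPM level, at which neither interval lies wholly beyond 2-fold. The one without a STAT5 region, on chromosome 3 from 37130100 to 37130399, had 687 STAT3 and 453 STAT5 reads. Since 400 bp can hold at most 800 reads, these ratios are compressed, and a region not called here need not be equal. At the 2327 sites with over 400 of 800 positions taken, a correction chosen after the data were seen raised STAT3-higher sites from 35 to 58.

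The tallest STAT5 regions were more often higher with STAT5: 7 of the 10 were called so, and 9 overlapped a STAT3 region. The tallest, on chromosome 5 from 53881850 to 53882499, had 780 STAT5 and 554 STAT3 reads, a 1.63 times higher RPM (interval 1.46 to 1.82). On chromosome 1 the neighbouring regions from 108503400 to 108503999 and from 108508950 to 108509749 had 771 and 773 STAT5 reads against 96 and 181 STAT3 reads, an RPM 9.29 times (7.51 to 11.6) and 4.94 times (4.20 to 5.84) as high. STAT5 was also higher on chromosome 17 from 35342000 to 35342649, where 767 STAT5 reads met 125 STAT3 reads and no STAT3 region was called (7.10 times, 5.87 to 8.65). STAT5 was higher, at regions called with both antibodies, on chromosome 12 from 52948750 to 52949399 (761 and 209 reads, 4.21 times) and on chromosome 10 from 92690450 to 92691049 (773 and 222, 4.03 times). A further pair of regions, on chromosome 15 from 62102800 to 62103349 and on chromosome 2 from 153118000 to 153118649, had 766 and 770 STAT5 reads, 2.69 and 2.37 times the STAT3 level. The regions on chromosome 4 from 32378200 to 32378749 (769 STAT5 and 643 STAT3 reads) and on chromosome 9 from 107236750 to 107237049 (762 and 450) were not called higher. With at most 800 reads possible in 400 bp, these ratios are compressed, and the number called higher depends on this ceiling. At the 2327 sites with over 400 of 800 positions taken, the same correction raised STAT5-higher sites from 1478 to 1736.

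**Figure D4:**
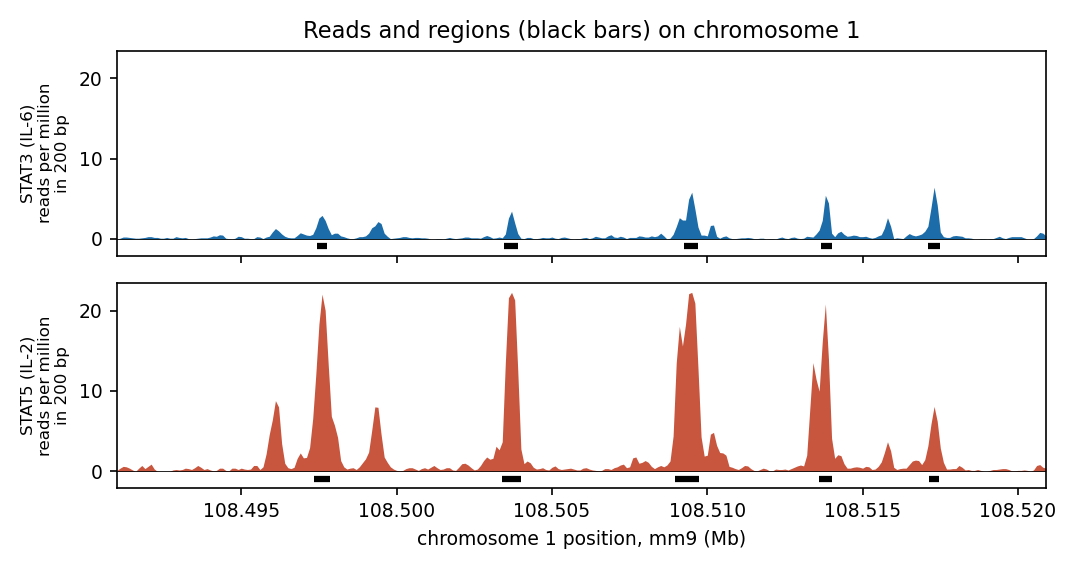
RPM in 200 bp along 29.9 kb of chromosome 1 (mm9, from 108491000 to 108520900), STAT3 after IL-6 above and STAT5 after IL-2 below on the same scale, with called regions as black bars. Each of the 5 STAT3 regions overlaps 1 of the 5 STAT5 regions, and the STAT5 regions with 771 and 773 reads in 400 bp are among the 10 tallest of that library. Peaks away from the bars were not called: the 200 bp around 108513400 held 243 STAT5 reads.

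Sites with the largest ratios were regions of 1 library only. This largely follows from the choice: they had 0 to 5 reads of the other antibody, while called regions had at least 12 of their own. For STAT3 the first was on chromosome 15 from 79928000 to 79928349, with 159 STAT3 and 3 STAT5 reads, a ratio of 45.8 (interval 15.4 to 224). It was followed by chromosome 11 from 5874050 to 5874449 (117 and 3 reads, 33.7, 11.3 to 166), chromosome 4 from 47028050 to 47028499 (92 and 2 reads), and chromosome 12 from 104511200 to 104511599 (143 and 5 reads). A site on chromosome 5 from 117575650 to 117575949 had 43 STAT3 and 0 STAT5 reads. It was 12.4-fold higher with STAT3 against the floor of 3 reads, and the exact interval of the ratio began lower, at 9.65. The 10 STAT3 sites had 40 to 159 STAT3 reads and 0 to 5 STAT5 reads.

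The STAT5 sites of this kind were taller, with 161 to 425 STAT5 reads and 0 to 3 STAT3 reads. The site on chromosome 1 from 80992450 to 80992899 had 204 STAT5 and 0 STAT3 reads. It was 78.7-fold higher with STAT5 against the floor of 3 reads, and the exact interval of the ratio began lower, at 63.4. On chromosome 18 from 14830550 to 14831049 there were 425 STAT5 and 3 STAT3 reads, a ratio of 164 (interval 55.7 to 798), and on chromosome 6 from 54713850 to 54714399 there were 382 and 3. On chromosome 13 from 112315750 to 112316349 there were 330 STAT5 and 2 STAT3 reads, and on chromosome 7 from 117047750 to 117048449 there were 288 and 1. At 4 of the 10 sites no STAT3 read was seen, where the flanks averaged 4.85 STAT3 reads over all sites. Sites with 100 or more reads of one antibody and the other at or below its flank mean numbered 511 of 18127 (2.82%, exact 95% interval 2.58 to 3.07%) for STAT5 and 2 of 12840 (0.0156%, 0.00189 to 0.0563%) for STAT3. These numbers are not on equal terms. The flank means were 4.85 STAT3 and 3.64 STAT5 reads, and mean counts over all sites were 11.3-fold over the flanks for STAT3 and 21.1-fold for STAT5.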

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

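The mitochondrial genome was left out of the region calls, and held 4435 STAT3 and 4433 STAT5 combinations of position and strand with a read, of which 1464 were the same in both libraries. Mismatches were not used in the comparisons either. At 309 nuclear positions in the STAT3 library and 205 in the STAT5 library, 5 or more reads carried a mismatch and made up at least 80% of the reads there, and 139 of these positions were common to both libraries. These counts assume that the match descriptor runs in the orientation of the read, chosen because 1761 STAT3 mismatch positions were then seen on both strands, against 473 in the orientation of the genome. No control library was analysed here; each of these counts is listed because it lies above the limit of 3 that a count of 0 allows. Neither was part of the planned comparisons, and no explanation was tested.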

How the results depend on the processing

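The restriction to the tallest regions, the correction for positions already taken and the removal of sites with over 400 of 800 positions taken were chosen after the data were seen; the other alternatives were planned. In 35 planned recalculations the value stayed within its limit, 1.5 times for a count and the exact 95% interval for a share, and in 19 it moved. STAT5 had more regions than STAT3, and more sites on its side, under each of these planned changes that gave such counts. STAT5-higher sites ranged from 16177 to 27915, and per STAT3-higher site from 5.53 to 41.4. A minimum fold of 8 lowered the regions to 24023 for STAT3 and 41582 for STAT5, the overlap to 67.0% and 38.7%, and the STAT3-higher sites to 1286; fewer regions follow from the threshold itself. With the genome-wide mean alone there were 90151 STAT3 regions, up to 11500 bp wide, and the overlap was 75.8% of STAT3 and 67.7% of STAT5 regions. Overlap shares of STAT3 and STAT5 regions were 69.7% and 56.1% at an adjusted p of 1e-10 or below, 74.1% and 56.7% with STAT3 thinned to equal depth, 67.4% and 54.3% with summits within 100 bp, 69.0% and 55.6% with a reciprocal overlap of 50%, and 52.4% and 52.3% among the tallest 20000 regions of each. With a fragment length of 150 bp the STAT5 share was 57.8%. STAT3-higher sites numbered 674 under scaling by bins without a region, which lowers STAT3 to 0.723 of its RPM level, and 4906 with an interval beyond 1.5-fold. Beyond what each threshold or rule fixes, the cause was not tested. Counts were corrected for positions already taken only at the 2327 sites with over 400 of 800 positions taken, and all other sites kept their exact calls. The correction treated the 800 positions as equally likely to be taken and used an approximate interval. It raised the calls at the 2327 sites from 1513 to 1794, which gave 2086 STAT3-higher and 21853 STAT5-higher sites in all. With the 2327 sites left out there were 2028 and 20117. Keeping all copies of a read could not be run because the files hold none, and the alternatives for gene lists, promoters and motifs were not run without mm9 genes and sequence. No paired analysis was possible because each group has 1 library. Depth limits weak sites: simulated sites of 10 reads, each apart from other sites, were found in 13.5% of cases.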

Other observations

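The tests of library depth, of the cytokine and of the region threshold in this part were chosen after the results were seen; the others were written before.

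Linking the 85657 sites within 10 kb gave 37224 groups, of which 18787 were single sites and 657 held 10 or more sites, 8542 in all. These numbers were not compared with a random placement of sites. The groups named here were chosen after the values were seen, as those with most sites or most sites higher on one side. The largest lay on chromosome 12 from 74666350 to 74881199 and held 51 sites, of which 31 were STAT3 regions and 43 STAT5 regions; 21 sites were higher with STAT5 and 0 with STAT3. On chromosome 2 from 11523700 to 11594099 there were 23 sites, 16 of them higher with STAT5. The opposite was seen on chromosome 15 from 100428800 to 100458099, where 5 of 10 sites were higher with STAT3 and 0 with STAT5. On chromosome 11 from 103094250 to 103208299 both kinds stood side by side, with 5 of 25 sites higher with STAT3 and 3 with STAT5.

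Neighbouring sites tended to differ in the same direction. Of 3978 pairs of adjacent sites within 10 kb that were both called, 89.2% had the same direction, against 84.1% (range 82.6 to 85.7%) in 100 shuffles of the calls. In 46 pairs both were higher with STAT3, against 30.2 on average and at most 43 in the shuffles. No minimum distance was set, and sites closer than the 400 bp counting width share reads. The shuffles do not allow for this, so the test cannot separate a shared direction from shared reads. Whether tall STAT5 sites with STAT3 reads at or below the flank level lie apart from other sites was tested and not borne out at the size set beforehand. Their median distance to the nearest site was 5.25 kb (95% bootstrap interval 4.75 to 5.90 kb), 1.25 times the 4.20 kb (3.70 to 4.75 kb) of shared sites matched on STAT5 reads, where 1.5 times had been set.

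More sites were higher with STAT5 than with STAT3. Library depth is argued against, since the STAT5 library was the shallower one and, at equal depth, 10.5 sites were higher with STAT5 for each one higher with STAT3. A single common difference in immunoprecipitation yield was examined, but the test cannot decide it. STAT3 reads were expected as the flank level plus a common factor times the STAT5 excess. By the exact Poisson interval of the STAT3 count, 23163 sites lay below 50% of the expectation and 4437 above 2 times it. This is a ratio of 5.22. The factor of 1.11 was the median at sites called with both antibodies, which were chosen for having a STAT3 region. Sites with few STAT3 reads then fall below the expectation by construction, so this ratio largely restates the calls. The antibodies and the cytokine given before fixation cannot be told apart, because they changed together, with 1 library of STAT3 after IL-6 and 1 of STAT5 after IL-2.

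At 511 sites with 100 or more STAT5 reads, STAT3 reads were at or below the flank level, with medians of 143 STAT5 and 3 STAT3 reads. Reads placed there from diverged repeats or other DNA of differing sequence are argued against by their mismatches, which were 0.896 times as frequent as at shared sites (1.57%, exact 95% interval 1.48 to 1.65%, against 1.75%, 1.73 to 1.76%). Reads from identical copies would match exactly, so the test does not cover them. How the aligner treated such reads is not given in the sources used here. Local pile-ups without the strand shift of fragments are argued against too, since the plus and minus strand ends lay 113 bp apart (95% bootstrap interval 112 to 114 bp), against 102 bp at shared sites. Binding of the STAT5 antibodies to another protein was not tested, and binding by STAT5 at sites with STAT3 reads at flank level remains a hypothesis.

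Part of the STAT5-only sites may be sites where STAT3 reads were present but below the threshold for a region. That threshold is higher near other sites, because the local means include them. STAT3 reads exceeded 2 times the flank mean at 48.6% of them, against 9.02% of flank windows. Flank windows were kept only where they met no region, while these sites may lie beside a STAT3 region. The contrast therefore cannot separate STAT3 reads of the site itself from those of a neighbour. At 25.5% of them STAT3 reads were at or below the flank mean, against 67.0% of flank windows, and counts this low do not separate a weak STAT3 signal from none.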
